A study of Homo sapiens with 12 samples.

How the data were processed

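RNA of a conditionally immortalized human podocyte line was sequenced in 12 libraries, 3 for each of 4 groups. The line carries a temperature-sensitive SV40 large-T antigen, grows at 33 °C and was held at 37 °C for 12 days to differentiate. A stable Tet-On construct expressed either eGFP (the control line) or YAP5SA, a form of the transcriptional co-activator YAP that resists inhibition by the Hippo kinases, here with a FLAG tag and a nuclear localization signal. Each line was kept without doxycycline or given 0.1 µg/ml for 24 hours. Libraries were made from 1000 ng of total RNA with a poly(A) mRNA kit, per the labels' protocols. The labels number the replicates 1 to 3 in every group but do not say whether they are separate cultures, so p-values measure only the spread between these samples, which may be technical.

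The authors deposited one table of whole-number counts of reads per gene for all 12 libraries. Per the submitters' processing notes, DRAGEN, featureCounts, Subread, limma and DESeq2 were used with the human build GRCh38 (hg38); versions, the role of each tool and the strand setting are not given in the sources used here. Reads of a gene and of its antisense partner can therefore not be told apart. The table has 62656 genes, of which 24935 had no count. A table of identifiers held 62639 of them, 42303 with a symbol other than the identifier. Positions, transcript GC content and gene types came from GENCODE 29 on GRCh38, which held 58220 of them. Totals ranged from 24477592 to 25993413 counts per library. Rows of XIST, TSIX and chromosome Y are left out of the printed tables.

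Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the groups (17470 genes), scaled by TMM and fitted with a robust quasi-likelihood model over all 12 libraries with 8 residual degrees of freedom. The common biological coefficient of variation was 7.48%. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Levels are in CPM, counts scaled to a common library size, here with TMM factors, and errors are the standard error (SE) of a log2 fold change or the standard deviation (SD) of CPM over 3 libraries. The 5 comparisons were doxycycline against none in the YAP5SA line, the same in the GFP line, the difference between those effects (the interaction), and YAP5SA against GFP without and with doxycycline. The test was run first on simulated data, in which 67, 67 and 66 genes were changed by 0.5, 1 and 2 on the log2 scale. Simulated libraries were drawn independently, with no effect of the replicate number. In the induction comparison the test recovered 45, 60 and 66 of these genes (67.2%, 89.6% and 100%), with 13 unchanged genes called among the 17107 tested. For the interaction the shares were 41.8%, 83.6% and 98.5%, with 10 unchanged genes called, and between the lines with doxycycline 61.2%, 91.0% and 98.5%, with 8.

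The 26 gene lists were fixed before the data were examined. They cover YAP/TAZ targets, Hippo components and TEAD factors, podocyte, parietal epithelial, tubule, endothelial, mesangial and fibroblast, and leukocyte genes, cell cycle, p53 targets, collagen and matrix, matrix proteases, actin and adhesion, cytokines, NF-kB, interferon, complement, growth factors, TGF-beta, ATF4, mitochondrial and nuclear oxidative phosphorylation, cholesterol synthesis, glycolysis and hypoxia, immediate early and heat shock genes, and apoptosis regulators. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists. Genes named are the 12 largest rises and falls of the induction and interaction comparisons (6 for the others) with non-overlapping libraries and at least 2 CPM in the higher group, up to 4 members of each list with the smallest p, and a fixed set of YAP targets and podocyte markers; some of these are not reported here.

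Alternatives were RLE and upper-quartile scaling, no filter or a stricter one on low counts, DESeq2 1.42.0, limma-voom, a fold-change minimum, the groups compared alone, YAP1 left out of library sizes, the replicate number as a block and each library left out. A GC correction, a blocked fit of the GFP libraries alone and a block in the GFP line only were added after the data were seen. Deviations of same-numbered libraries from their group means correlated at 0.23, 0.42 and 0.41 between the GFP groups, so those are treated as paired. The labels' replicate numbers are the source of that pairing. The other comparisons did not meet the rule of 0.1 for every number and are not treated as paired.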

Results

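The transcriptome was measured in differentiated human podocytes, the filtration-barrier cells of the glomerulus, carrying a doxycycline-inducible eGFP or YAP5SA. The groups were GFP without doxycycline, GFP with doxycycline, YAP5SA without doxycycline (uninduced) and YAP5SA with doxycycline (induced), with 3 libraries each. Totals were 24477592 to 25177086 counts in the GFP libraries and 25493014 to 25993413 in the YAP5SA libraries. The first principal component held 49.8% of the variance. Its group means were -26.4 for GFP without doxycycline, -25.1 for GFP with it, 7.07 for uninduced and 44.4 for induced YAP5SA.

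**Figure D1:**
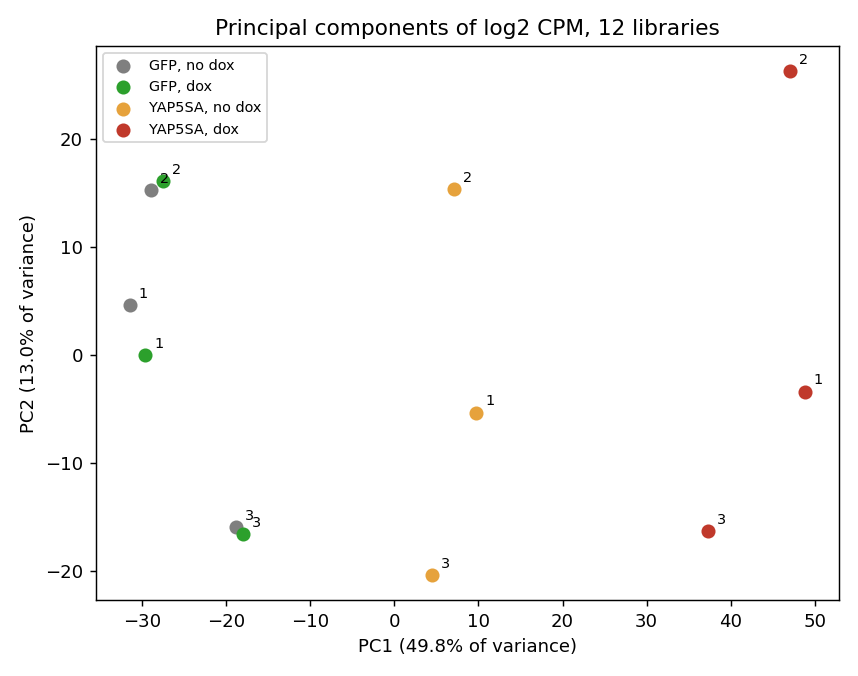
Principal component 1 (49.8% of variance, x axis) against component 2 (y axis) of log2 CPM, with 1 point per library, coloured by group and numbered by replicate. Both GFP groups lie at the left, the uninduced YAP5SA libraries in the middle and the induced ones at the right.

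The transgene was read through YAP1 (ENSG00000137693, chromosome 11, 102110461 to 102233423 on GRCh38), whose row can count endogenous and transgene transcripts together. YAP1 rose from 314 ± 82.1 CPM to 1466 ± 432 CPM (SD, n = 3) with doxycycline in the YAP5SA line, a log2 fold change of 2.22 ± 0.38 (SE, edgeR adjusted p = 0.00374). The induced libraries held 1757, 1672 and 970 CPM. In the GFP line YAP1 was 275 CPM without and 272 CPM with doxycycline (log2 fold change -0.02 ± 0.36). eGFP is not a row of the table used here, so its induction was not checked.

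The main question was which transcripts change when YAP5SA is induced in differentiated podocytes. Of 21 known YAP/TAZ targets 14 rose, though as a list they did not pass with an estimated correlation (adjusted p = 0.0929). Of 27 genes for Hippo pathway components and the TEAD factors that YAP binds, 13 rose and 3 fell. Some members of the p53, hypoxia, cytokine and TGF-beta lists fell, and these lists passed at the preset correlation only. Induction changed 3338 of 17470 genes, 1717 higher and 1621 lower, with a median absolute log2 fold change of 0.34 among them. Of these, 268 changed by at least 1 on the log2 scale, 102 higher and 166 lower. Upper-quartile scaling also turned the majority, with 1654 higher and 1717 lower. So did the replicate block over 12 libraries (4878 genes, 2425 higher and 2453 lower), though the rule for pairing was not met on induction.

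Of 21 measured YAP/TAZ targets, 14 rose and 0 fell (16 and 0 adjusted over the list alone, camera adjusted p = 1.75e-13, and adjusted p = 0.0929 with an estimated correlation). The matricellular genes CCN1 and CCN2 rose by 0.43 ± 0.06 and 0.60 ± 0.09 on the log2 scale, the angiomotin gene AMOTL2 by 0.74 ± 0.08, and the receptor tyrosine kinase gene AXL by 0.29 ± 0.05. ANKRD1 rose by 0.95 ± 0.28 (adjusted p = 0.0423), a call that ended without any 1 of the YAP5SA libraries (0.91 to 1.03) and with no filter on low counts (0.95). Among 27 Hippo components and TEAD factors, 13 rose and 3 fell (14 and 3 adjusted over the list alone, camera adjusted p = 1.67e-07, and adjusted p = 0.0368 with an estimated correlation). They included the kinase gene LATS2 at 0.84 ± 0.07, the transcription factor gene TEAD1 at 0.62 ± 0.04 and WWC1 at 0.53 ± 0.04. LATS2, AMOTL2 and PTPN14 are also in the list of YAP/TAZ targets, so in every comparison these lists are not independent. The YAP paralog WWTR1 rose by 0.15 ± 0.03, a call that a correction for GC content ended (0.10 ± 0.04, a smaller fold), as did a fit of the YAP5SA libraries alone (0.14).

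**Figure D2:**
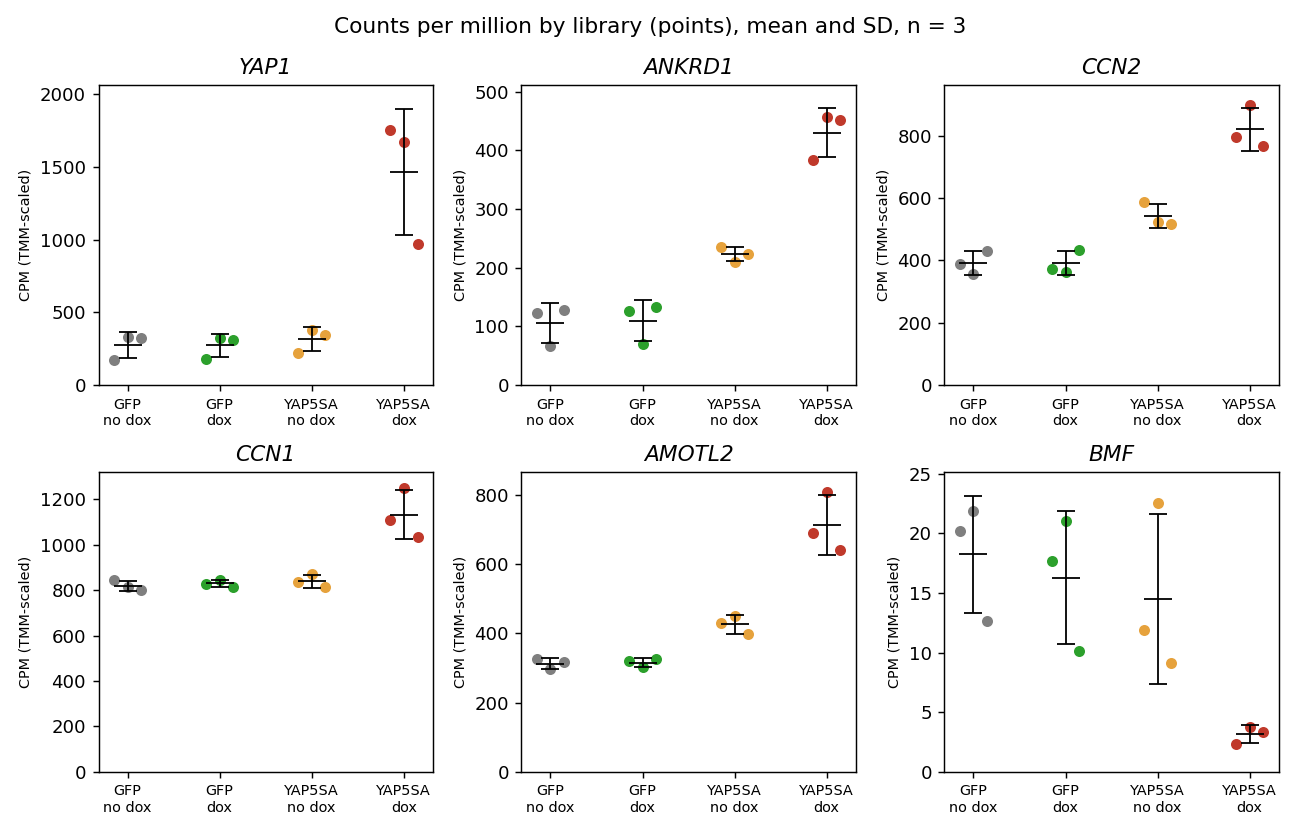
CPM (y axis, from 0) of YAP1, ANKRD1, CCN2, CCN1, AMOTL2 and BMF in each library (points) of the 4 groups (x axis), with the group mean and SD as bars. YAP1 lay between 970 and 1757 CPM in the induced libraries, and mean CCN2 was 391, 390, 543 and 821 CPM from left to right.

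By the rule for named genes, the largest rises after YAP1 included the homeobox gene LHX4 (1.95 ± 0.26), the keratin gene KRT4 (1.93 ± 0.41), the leukocyte integrin gene ITGB2 (1.92 ± 0.38), NAV3 (1.53 ± 0.11), the tight junction gene CGN (1.50 ± 0.18), the chemokine gene CCL11 (1.49 ± 0.23) and ANKRD2 (1.47 ± 0.12). RASAL2-AS1 (1.93 ± 0.29) and PLCE1-AS1 (1.55 ± 0.29) also rose, but without a stated strand setting their reads cannot be told from those of the opposite strand. The pro-apoptotic gene BMF fell by 2.20 ± 0.45 on the log2 scale, from 14.5 ± 7.12 to 3.14 ± 0.768 CPM (SD). The claudin gene CLDN4 fell by 2.02 ± 0.25, the mTORC1 inhibitor gene DDIT4 by 1.72 ± 0.24 and the growth factor gene GDF5 by 1.50 ± 0.15. Among 14 apoptosis regulators 2 rose and 4 fell (5 and 8 adjusted over the list alone, camera adjusted p = 0.409). Anti-apoptotic BCL2 rose by 0.84 ± 0.12 and CFLAR by 0.30 ± 0.06, and pro-apoptotic BCL2L11 fell by 0.93 ± 0.17 and PMAIP1 by 0.31 ± 0.05.

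Several lists moved down at the preset correlation only. Of 19 glycolysis and hypoxia genes, 1 rose and 9 fell (2 and 11 adjusted over the list alone, camera adjusted p = 1.79e-07, and adjusted p = 0.253 with an estimated correlation), led by PFKFB4 (-1.12 ± 0.07), BNIP3 (-0.44 ± 0.05) and the glucose transporter gene SLC2A1 (-0.40 ± 0.05). Of 20 p53 targets, 0 rose and 8 fell (1 and 12 adjusted over the list alone, camera adjusted p = 1.03e-04, and adjusted p = 0.309 with an estimated correlation), including TP53INP1 (-0.60 ± 0.05). Of 20 cytokine genes, 0 rose and 5 fell (0 and 7 adjusted over the list alone, camera adjusted p = 1.59e-04, and adjusted p = 0.253 with an estimated correlation), including CX3CL1 (-0.95 ± 0.12) and CSF2 (-1.41 ± 0.20). Of 16 TGF-beta and SMAD response genes, 1 rose and 9 fell (1 and 9 adjusted over the list alone, camera adjusted p = 0.00528, and adjusted p = 0.253 with an estimated correlation), including KLF10 (-0.43 ± 0.06) and SNAI1 (-0.65 ± 0.12).

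**Figure D3:**
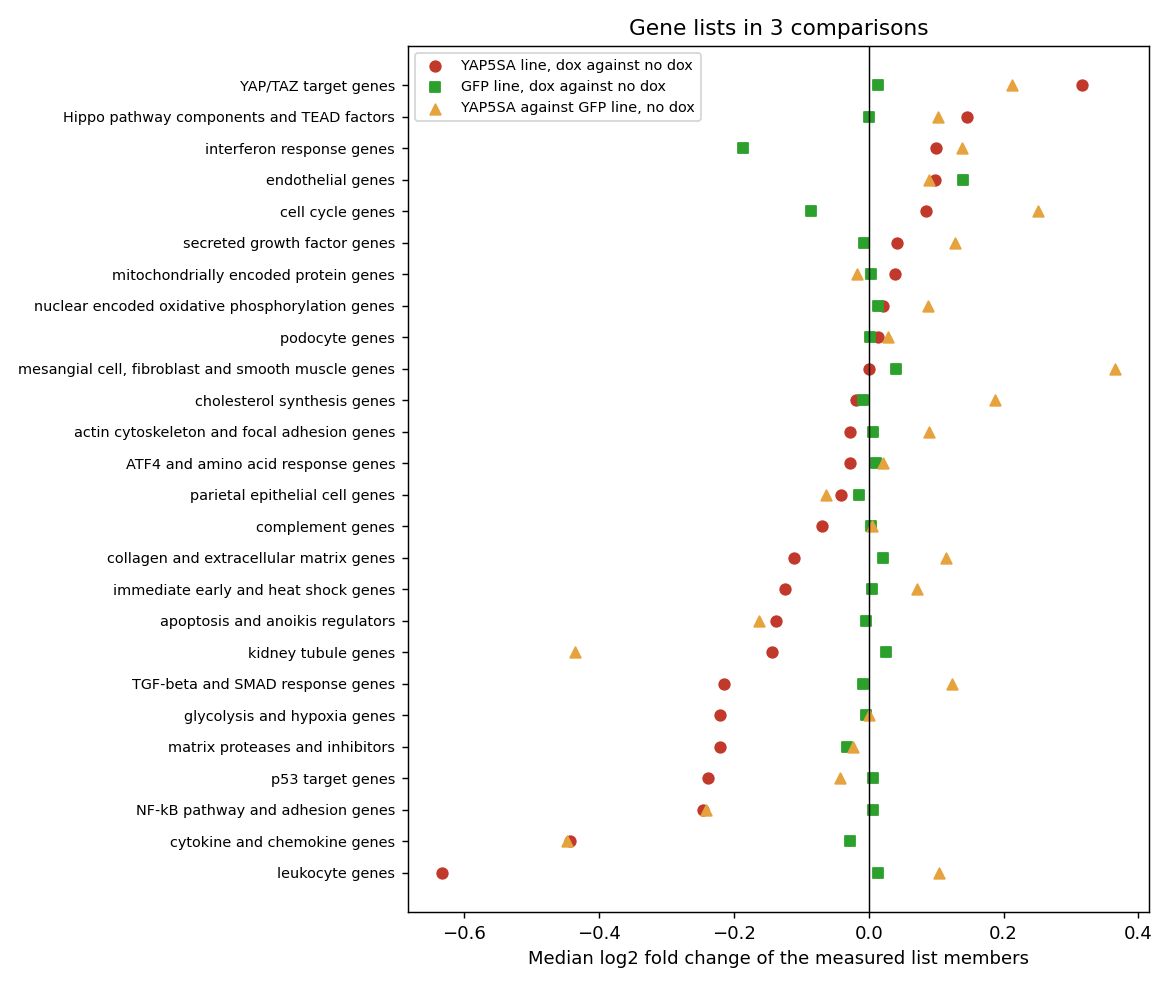
Median log2 fold change (x axis) of the measured members of each gene list (y axis) on doxycycline in the YAP5SA line (circles), on doxycycline in the GFP line (squares) and between the lines without doxycycline (triangles). The median of YAP/TAZ targets was 0.32, 0.01 and 0.21, in that order.

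Some matrix and contractile genes changed, while their lists did not pass. Of 29 collagen and matrix genes, 3 rose and 8 fell (3 and 8 adjusted over the list alone, camera adjusted p = 0.545), with rises in COL12A1 (0.78 ± 0.08), THBS1 (0.52 ± 0.06) and FBLN5 (0.71 ± 0.10) and a fall in COL6A2 (-0.25 ± 0.04). Of 17 matrix proteases and inhibitors, 4 rose and 4 fell (4 and 7 adjusted over the list alone, camera adjusted p = 0.41). The protease inhibitor gene TIMP3 rose by 0.64 ± 0.07, and the protease genes MMP2 and MMP14 fell by 0.64 ± 0.07 and 0.42 ± 0.06. Of 10 mesangial, fibroblast and smooth muscle genes, 4 rose and 0 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.114), including PDGFRB (0.90 ± 0.13). Of 28 actin cytoskeleton and focal adhesion genes, 5 rose and 4 fell (5 and 7 adjusted over the list alone, camera adjusted p = 0.694), with CALD1 at 0.26 ± 0.05 and TPM4 at -0.17 ± 0.04.

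Podocyte and parietal epithelial genes changed in both directions on induction. Of 26 measured podocyte genes, 4 rose and 4 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.823). The basement membrane collagen gene COL4A4 rose by 0.56 ± 0.06 and the junction gene TJP1 by 0.30 ± 0.03, and the intermediate filament gene NES fell by 0.81 ± 0.08 and KIRREL1 by 0.33 ± 0.04. SYNPO (0.10 ± 0.06) and PODXL (-0.34 ± 0.36) did not pass. The slit diaphragm gene NPHS1 (18 reads in 12 libraries) and the podocyte transcription factor gene WT1 (71 reads) were too low to test. Of 21 parietal epithelial genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.31). CDH6 fell by 1.39 ± 0.17, KRT19 by 0.55 ± 0.05 and CD44 by 0.38 ± 0.06, and ANXA3 rose by 0.28 ± 0.04. Of 28 secreted growth factor genes, 9 rose and 4 fell (9 and 5 adjusted over the list alone, camera adjusted p = 0.203), with rises in EDN1 (0.56 ± 0.05), NRG1 (0.63 ± 0.07) and WNT5B (0.38 ± 0.05) and a fall in ANGPTL4 (-0.91 ± 0.10).

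Doxycycline in the GFP line served as the control for the drug and for expressing a transgene. The YAP targets named above did not pass there: the log2 fold change of CCN1 was 0.02 ± 0.06, that of AMOTL2 0.01 ± 0.08 and that of ANKRD1 0.05 ± 0.28. edgeR called 0 of 17470 genes, with 282 (1.61%) at an unadjusted p under 0.05, a smaller share than the 0.05 that no effect would give. This fit did not use the pairing of the GFP libraries, so its 0 calls do not exclude small effects of doxycycline. Calls were 0 by limma-voom and 1 by DESeq2. That gene was PGK1, a glycolytic enzyme (0.37 ± 0.05, edgeR adjusted p = 0.127), which the replicate block over 12 libraries also called. With the block in the 6 GFP libraries alone, an alternative added after seeing the data, 20 genes were called. Of 21 YAP/TAZ targets 1 fell there, F3 (-0.14 ± 0.03), and 0 rose (camera adjusted p = 0.297); F3 was -0.14 ± 0.19 in the unpaired fit. Of 25 interferon response genes, 9 fell in that paired fit, with a list median of -0.18 (camera adjusted p = 1.04e-47, and adjusted p = 0.783 with an estimated correlation). In the unpaired fit 0 of them passed, and the list had an adjusted p of 2.67e-08, or 0.966 with an estimated correlation; without replicate 3 of GFP without doxycycline it was 0.212.

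The interaction asked which genes responded differently to doxycycline in the YAP5SA and GFP lines. It called 1202 genes, 629 with a more positive and 573 with a more negative log2 change in the YAP5SA line than in the GFP line. CCN1 (0.41 ± 0.08), CCN2 (0.60 ± 0.13), AMOTL2 (0.73 ± 0.11) and AXL (0.29 ± 0.06) passed. YAP1 (2.24 ± 0.52, adjusted p = 0.0362) passed too, but with no filter on low counts (2.25) it did not. Nor did it in 10 of 12 fits that each left out 1 library (2.02 to 2.40 in those). ANKRD1 (0.89 ± 0.40, adjusted p = 0.24) did not pass, but did with the replicate block in the GFP line only, added after seeing the data (0.89 ± 0.09). Of 21 YAP/TAZ targets, 9 had a more positive and 0 a more negative change (13 and 0 adjusted over the list alone, camera adjusted p = 4.34e-12, and adjusted p = 0.123 with an estimated correlation). The list of Hippo components and TEAD factors gave an adjusted p of 2.45e-07, and adjusted p = 0.0428 with an estimated correlation. Leaving out 1 library gave 750 to 1387 genes. Counts were lowest without replicate 3 of GFP without doxycycline (768), replicate 1 of GFP with it (750) or replicate 1 of uninduced YAP5SA (781). Among other settings, the majority turned with upper-quartile scaling (609 more positive, 616 more negative), without replicate 3 of induced YAP5SA (684 and 703) and at a log2 difference of at least 1 (47 and 80). The replicate block over 12 libraries called 2418 genes and turned the majority too (1162 and 1256), though the rule for pairing was met only in the GFP line. Across genes, which are not independent replicates, fold changes on doxycycline in the lines correlated at Pearson's r = 0.0515 and Spearman's rho = 0.0605.

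Comparing the lines without doxycycline asked how they differ at baseline, including any leak of the construct. The uninduced YAP5SA line differed in 1512 genes, 1056 higher and 456 lower. YAP1 itself differed by 0.19 ± 0.36 and did not pass. Of 21 YAP/TAZ targets, 12 were higher and 0 were lower (13 and 1 adjusted over the list alone, camera adjusted p = 6.93e-11, and adjusted p = 0.0621 with an estimated correlation), including LATS2 (0.61 ± 0.07), CCN2 (0.47 ± 0.09), AMOTL2 (0.45 ± 0.08) and F3 (1.32 ± 0.19). CCN1 differed by 0.03 ± 0.06 and did not pass. Of 27 Hippo components and TEAD factors, 9 were higher and 0 were lower (11 and 1 adjusted over the list alone, camera adjusted p = 3.30e-05, and adjusted p = 0.0387 with an estimated correlation). Of 29 matrix genes, 9 were higher and 3 were lower (11 and 3 adjusted over the list alone, camera adjusted p = 1.17e-04, and adjusted p = 0.0177 with an estimated correlation), with FBLN5 at 2.20 ± 0.12 and COL12A1 at 0.90 ± 0.08. Of 10 mesangial, fibroblast and smooth muscle genes, 6 were higher and 0 were lower (6 and 1 adjusted over the list alone, camera adjusted p = 8.31e-07, and adjusted p = 0.0139 with an estimated correlation), with PDGFRB at 1.12 ± 0.15. Lists that were lower passed at the preset correlation only. Of 20 cytokine genes, 1 were higher and 4 were lower (1 and 6 adjusted over the list alone, camera adjusted p = 3.25e-05, and adjusted p = 0.144 with an estimated correlation), with CX3CL1 at -0.97 ± 0.11 and CXCL8 at -0.77 ± 0.16, the latter a call that ended in 4 of 6 fits without 1 library (-0.79 to -0.67) and with no filter on low counts (-0.78). Of 15 NF-kB and adhesion genes, 0 were higher and 2 were lower (0 and 2 adjusted over the list alone, camera adjusted p = 2.85e-04, and adjusted p = 0.332 with an estimated correlation), and of 14 apoptosis regulators, 1 were higher and 2 were lower (1 and 5 adjusted over the list alone, camera adjusted p = 0.0146, and adjusted p = 0.172 with an estimated correlation). Of 8 tubule genes, 0 were higher and 2 were lower (0 and 3 adjusted over the list alone, camera adjusted p = 0.0366, and adjusted p = 0.144 with an estimated correlation). The call of the apoptosis list ended without replicate 2 of uninduced YAP5SA (adjusted p = 0.0516), and that of the tubule list without replicate 1 of GFP without doxycycline (0.0532). Keratin genes KRT18 (0.95 ± 0.11) and KRT8 (0.46 ± 0.06), which have near-identical pseudogenes that can share their reads, were higher. ANKRD1 (1.08 ± 0.28) was higher, a call that ended without any 1 of the libraries compared (0.83 to 1.23). NPAS1 (3.63 ± 0.55), STXBP6 (3.12 ± 0.52) and KISS1 (2.27 ± 0.31) were among the largest differences, and the BMP antagonist gene CHRD was lower (-1.49 ± 0.28). Each fit that left out 1 library gave a lower count (607 to 1451). The count was lowest without replicate 1 (718) or 2 (678) of GFP without doxycycline or replicate 1 of uninduced YAP5SA (607). It was higher with the replicate block over 12 libraries (2994 genes, 1839 higher and 1155 lower), though the rule for pairing was not met between the lines.

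The lines were also compared with doxycycline in both, which holds the drug constant. Here 6691 genes differed, 3471 higher and 3220 lower in the YAP5SA line. Of these, 964 were also higher and 397 also lower without doxycycline, so the count includes differences between the lines that were present before induction. The majority turned with upper-quartile scaling (3025 higher, 3596 lower) and at a log2 difference of at least 1 (505 and 586). YAP1 (2.43 ± 0.38), ANKRD1 (1.97 ± 0.29), CCN2 (1.07 ± 0.09) and AMOTL2 (1.18 ± 0.08) were higher. Of 21 YAP/TAZ targets, 15 were higher and 0 were lower (15 and 0 adjusted over the list alone, camera adjusted p = 1.16e-16, and adjusted p = 0.0352 with an estimated correlation). The amino acid transporter gene SLC7A5 was 2.16 ± 0.17 higher, and KRT4 (4.96 ± 0.63), STXBP6 (4.60 ± 0.51) and NPAS1 (4.54 ± 0.53) were among the largest differences. STXBP6 and NPAS1 were among the largest differences without doxycycline too. Of 20 cytokine genes, 0 were higher and 11 were lower (0 and 13 adjusted over the list alone, camera adjusted p = 3.14e-06, and adjusted p = 0.155 with an estimated correlation), with CXCL8, already lower without doxycycline, at -1.64 ± 0.17. AKR1C3 (-3.10 ± 0.31), CYP3A5 (-2.59 ± 0.30) and the chloride channel gene CFTR (-2.55 ± 0.32) were lower, as were KLHL4 (-2.63 ± 0.44) and FXYD2 (-2.58 ± 0.49).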

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

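The tests of the interferon response genes in the GFP line and the fit and splits with a block in that line alone were chosen after the result was seen; the other splits of the libraries were planned before it.

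The effect of doxycycline differed between the YAP5SA and GFP lines in 1202 genes by edgeR's test of the interaction. Of 100 splits of the libraries, the real one included, 7 gave at least as many genes, and the highest other gave 3179. That highest count points to a structure of the samples: it came from among the 8 other splits that kept the real YAP5SA labels. These moved only GFP libraries, so they still held the induction effect. The kept effect alone does not explain a count above the real 1202. These splits also took no account of the GFP pairing. Splits that changed the YAP5SA labels reached 672 at most. With the replicate block in the GFP line only, 1472 genes were called. Of the 80 splits that part every GFP pair 8 gave as many, with 1729 in the highest other; the 7 others as large again kept the real YAP5SA labels, and splits that changed them gave 0. Since splits that keep the induction effect make up 0.05 or more of either set, these tests decide nothing about chance.

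Among genes with a more positive change in the YAP5SA line than in the GFP line, the log2 difference of the doxycycline effects was 2.24 ± 0.52 for YAP1, 1.79 ± 0.48 for RASAL2-AS1, 1.68 ± 0.35 for CCL11, 1.57 ± 0.19 for ANKRD2, 1.51 ± 0.27 for CGN and 1.50 ± 0.17 for NAV3. It was 1.46 ± 0.20 for KIF17, 1.45 ± 0.14 for CRYBG2, 1.43 ± 0.36 for KL, 1.39 ± 0.20 for MAMDC2, 1.37 ± 0.18 for AJAP1 and 1.33 ± 0.34 for WWC2-AS2. The YAP targets CCN1, CCN2, AMOTL2 and AXL stood at 0.41, 0.60, 0.73 and 0.29.

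Among genes with a more negative change in the YAP5SA line than in the GFP line, the difference was -1.99 ± 0.34 for CLDN4, -1.68 ± 0.31 for SYT12, -1.63 ± 0.33 for DDIT4, -1.60 ± 0.32 for NEURL3 and -1.55 ± 0.36 for TUBB3. It was -1.45 ± 0.20 for GDF5, -1.44 ± 0.24 for LNCTSI, -1.38 ± 0.27 for CSF2 and -1.36 ± 0.34 for KCNK3. The urokinase gene PLAU (-1.38 ± 0.31) and C10orf55 (-1.42 ± 0.23) overlap on opposite strands of chromosome 10, so their reads cannot be told apart without a strand setting. The call ended in 10 fits that each left out 1 of the 12 libraries for YAP1, 8 for RASAL2-AS1, 7 for KL, 7 for WWC2-AS2, 4 for TUBB3, 10 for PLAU and 11 for KCNK3, the last with values of -1.55 to -1.13 in those fits. The call of PLAU also ended with the replicate block in the GFP line only (-1.38 ± 0.36). That of CCL11 ended without replicate 3 of GFP without doxycycline (1.59).

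By camera over the interaction, YAP/TAZ targets had an adjusted p of 4.34e-12, and adjusted p = 0.123 with an estimated correlation, and Hippo components and TEAD factors 2.45e-07, and adjusted p = 0.0428 with an estimated correlation. For p53 targets it was 1.05e-04, and adjusted p = 0.359 with an estimated correlation. The cytokine list gave 2.46e-04, and adjusted p = 0.319 with an estimated correlation. TGF-beta response genes gave 0.0105, and adjusted p = 0.293 with an estimated correlation, and glycolysis genes 7.79e-08, and adjusted p = 0.293 with an estimated correlation. The interferon list had a median difference of 0.23 and an adjusted p of 0.0208, and adjusted p = 0.718 with an estimated correlation. Its call ended without several single libraries, with the highest p of 0.254 without replicate 2 of uninduced YAP5SA.

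Interferon response genes were lower with doxycycline in the GFP libraries paired by replicate number, where 20 genes were called and 1 of the 4 swaps of labels within pairs gave as many, with 3 in the highest other; swaps this few cannot give a share under 0.05. MX1 (-0.33 ± 0.03), OAS3 (-0.30 ± 0.03) and MX2 (-0.74 ± 0.11) were among them, named after their values were seen. In each pair 18 of 25 members or more were lower, with medians of -0.10, -0.21 and -0.26. Members vary together (estimated correlation 0.357 in the paired fit), so these counts do not show a fall beyond noise in each pair. They therefore cannot decide whether a single pair carries the shift. In the unpaired fit the call of the list ended without replicate 3 of GFP without doxycycline (camera adjusted p = 0.212). With an estimated correlation, camera gave the list p = 0.0335 before and 0.783 after adjustment over the lists. Members varying together between libraries, with this many lists tested, may account for the fall of the list. An effect of doxycycline in any line also stays open: the list median in the YAP5SA line was 0.10, but YAP5SA was induced in the same libraries.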

How the results depend on the processing

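The GC correction, the paired fit of the GFP libraries alone and the block in the GFP line only were chosen after the data were seen, and the other settings before. Among the latter, 9218 values of named genes stayed on their side of the threshold, 398 no longer passed and 131 newly passed. For gene lists the counts were 1491, 51 and 28, and 1 more turned direction. Direction was compared only where a value passed in the main fit or in the other setting. Doxycycline in the GFP line gave 3 genes with no filter on low counts (PGK1, CEMIP and C21orf91), 1 by DESeq2, 1 with the replicate block (PGK1 in both) and 20 in the paired GFP libraries alone, where the pairing changed no list's call. The block over 12 libraries gave 2418 genes for the interaction (1162 more positive and 1256 more negative, which turned the majority), 2994 between the lines without doxycycline, 4878 on induction (2425 higher and 2453 lower, turned too) and 7931 between the lines with it. The block in the GFP line only gave 1472 genes for the interaction; among named genes it ended the calls of PLAU and SOD2, brought in ANKRD1, LUM, MCM7, FLNA, CNN2 and LTBP2, and changed no list's call. Outside the GFP line the rule for pairing was not met: deviations of same-numbered libraries correlated at -0.12, 0.35, 0.33 on induction, -0.29, 0.23, 0.28 without and -0.29, 0.23, 0.20 with doxycycline between lines, and replicate 1 did not correlate best with its own number, while replicates 2 and 3 did. The second principal component separated the numbers in all 4 groups (15.3 to 26.3 for replicate 2, -5.31 to 4.64 for replicate 1 and -20.4 to -15.9 for replicate 3), a hint from the data that a number marks something shared. Requiring an absolute log2 fold change of at least 1 left 268 genes on induction, 127 for the interaction, and 160 and 1091 between the lines without and with doxycycline, by construction.

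Leaving out each library in turn gave 2385 to 3363 genes on induction, 750 to 1387 for the interaction, 607 to 1451 and 5373 to 6345 between the lines without and with doxycycline, and 0 to 0 in the GFP line; fits with fewer libraries have less power. The cell cycle list, lower with doxycycline in the GFP line (adjusted p = 0.00229, and adjusted p = 0.966 with an estimated correlation), ranged from 3.70e-07 without replicate 2 of GFP with doxycycline to 0.602, in the opposite direction, without its replicate 1, and was 0.258 without replicate 2 of GFP without it. Relative to each gene's mean over the 12 libraries, the mean log2 level of this list was -0.54, -0.0085 and -0.082 in replicates 1 to 3 of GFP with doxycycline. In GFP without doxycycline it was -0.19, -0.0049 and -0.073. The fall thus lay mostly in replicate 1 of GFP with doxycycline, and why that library was lower was not tested. Comparisons of 3 against 3 libraries make 10 splits, too few for a share under 0.05: the real counts were 3338 on induction, 1512 and 6691 between the lines without and with doxycycline and 0 in the GFP line, the highest others 0, and splits as large 1, 1, 1 and 10.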

Other observations

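Tests of a leak of the construct and of GC content as a cause of the induction calls were chosen after the results were seen. That of shared libraries was not. The test of GC bias between the lines was set before its result, but it uses the GC correction, which was added after the data were seen.

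Other gene lists did not pass as lists on induction, though some members did. Of 30 cell cycle genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.476), with PCNA at -0.48 ± 0.07 and MCM7 at -0.39 ± 0.07; the list median was 0.08 while camera's direction was down. Of 15 NF-kB and adhesion genes, 0 rose and 2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.0533), with SOD2 at -0.46 ± 0.08; with no filter on low counts the list passed (0.0058). Of 19 immediate early and heat shock genes, 2 rose and 5 fell (3 and 7 adjusted over the list alone, camera adjusted p = 0.0715), with IER3 at -0.49 ± 0.05 and DUSP1 at 0.38 ± 0.05. Of 22 ATF4 and amino acid response genes, 3 rose and 4 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.531), with ATF3 at -0.53 ± 0.08. Of 25 interferon response genes, 0 rose and 1 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.545). Of 19 cholesterol synthesis genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.694). Of 14 complement genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.823), with CD55 at 0.67 ± 0.07; the list median was -0.07 while camera's direction was up.

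Markers of other kidney and blood cells did not pass as lists either. Of 8 tubule genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.583). Of 7 endothelial genes, 2 rose and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.809), with VWF at 0.84 ± 0.17 and ENG at -0.22 ± 0.05. Of 5 leukocyte genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.352). Of 13 mitochondrially encoded genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.456), and of 20 nuclear oxidative phosphorylation genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.798). Without doxycycline the YAP5SA line was higher in cholesterol synthesis genes, of which 6 were higher and 0 were lower (8 and 0 adjusted over the list alone, camera adjusted p = 2.85e-04, and adjusted p = 0.294 with an estimated correlation). TCF21 (0.89 ± 0.16) and the collagen genes COL4A3 (1.35 ± 0.15) and COL4A4 (0.90 ± 0.06) were higher there. These are in the podocyte list, of whose 26 measured members 3 were higher there and 2 were lower (5 and 3 adjusted over the list alone, camera adjusted p = 0.244). All 30 cell cycle genes had positive differences there, of which 1 passed (list median 0.25, camera adjusted p = 0.00123, and 0.408 with an estimated correlation). Lists of growth factors (5.17e-04), actin (0.00301), ATF4 (0.0104), matrix proteases (0.0146) and nuclear oxidative phosphorylation (0.0218) were higher by camera at the preset correlation only. The calls of the protease list (median -0.02) and the oxidative phosphorylation list ended without some single library.

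Without doxycycline the YAP5SA line already differed from the GFP line in the direction of induction: 478 genes were higher in both comparisons and 203 lower in both, against 104 and 42.3 for independent lists. Fold changes correlated across genes at 0.30, against -0.50 for simulated unchanged groups with the same shared libraries, which cannot be split. Noise of those libraries is argued against, since the covariance was 0.0358 and the simulated one -0.0218 (-0.0231 to -0.0203), a difference of 0.0576. GC bias between the lines is argued against too, since the covariance after GC correction was 0.0362. Leaky YAP5SA expression may account for it and stays open, since YAP1 differed by 0.19 with a 95% interval of -0.65 to 1.02, as does an untested difference between the lines. That interval takes no account of replicate numbers. In their order, YAP1 held 221, 375 and 345 CPM in uninduced YAP5SA and 173, 332 and 321 CPM in GFP without doxycycline. It was thus higher in the YAP5SA line at each number, but the rule for pairing was not met between the lines.

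Genes that rose on induction had a median transcript GC content of 44.5%, and genes that fell 53.1%. A GC bias as the whole cause of the calls is argued against, since 2717 of 3338 calls were kept after a correction per library, which called 3187 in all. Whether a bias made the GC difference itself cannot be told apart from a response of such genes, since the mean GC of the induced libraries was at most 49.708% and that of every other library at least 49.782%.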
